A study of Mus musculus with 30 samples.

How the data were processed

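RNA was measured in 27 ovarian tumours and 3 samples of normal ovarian surface epithelium of FVB/NJ mice on 30 Affymetrix mouse arrays with 45101 probe sets. Per the labels, tumour RNA came from flash-frozen pieces extracted with TRIZOL and a column, and normal RNA from surface epithelium taken by laser capture from 10 µm sections, with material of 20 sections per extraction and another RNA kit. For all samples 10 ng of RNA was amplified and labelled with an Ovation kit, and the labels give an RNA integrity number above 9. The deposited values are log2 probe set signals, per the submitters' processing notes made with RMA and Partek, whose versions, roles and order are not given in the sources used here. The unit was checked on the values, which run from 3.20 to 14.57 with array medians from 7.17 to 7.47, lower quartiles from 5.45 to 5.58 and upper quartiles from 9.52 to 9.65. No value was missing, and detection calls were not used here. The number of arrays limits the precision.

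Probe sets were named from the 2016 annotation of the array and the gene table supplied with it. Of the 45101 probe sets, 34945 had 1 gene, 932 had several and were left out, 9160 had no gene named here and were left out, and 64 were controls. For 34754 the Entrez identifier matched the gene table. Of each gene the probe set with the highest mean over all arrays was kept, which left 18193 genes, 9010 of them with more than 1 probe set. Genome coordinates were not used, and chromosomes were read from the gene table for 2 tests only. Some genes of the lists were not analysed here, and a list's measured number says how many were.

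Groups were taken from the genotype labels: 14 tumours of B1 fl/fl p53 fl/fl, 4 of K18 tg p53 fl/fl, 3 of B1 fl/fl p53 m/fl, 5 of B2 fl/fl p53 m/fl, 3 normal samples, and 1 tumour labelled B1 fl/+, K18, cp that has its own mean and enters no comparison. The labels do not spell out the genotype names, and do not say whether the 3 normal samples came from separate animals. The p values against them rest on a spread between samples that is pooled over all groups, to which tumours contribute most. They can be too small for genes whose normal samples spread more than the tumours. Tumour titles carry animal numbers of 3 forms, with 2 to 5 digits, with 6 digits, or with an R prefix, and these forms were treated as possible batches, since no date is given.

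Linear models were fitted with limma 3.58.1 in R 4.3.3 on the deposited values with 1 mean per group (lmFit, contrasts.fit, eBayes, with a prior of 2.038 degrees of freedom). Tests were two-sided, adjusted by Benjamini-Hochberg over all genes of a comparison, and a gene was called at an adjusted p under 0.05. The main comparison was the equal-weight mean of the 4 replicated tumour genotypes against normal epithelium. Each genotype was also set against normal epithelium. Genotypes were compared as B1 fl/fl p53 fl/fl against K18 tg p53 fl/fl, B1 fl/fl p53 m/fl against B1 fl/fl p53 fl/fl, and B2 fl/fl p53 m/fl against B1 fl/fl p53 m/fl. Stage IV was compared with lower stages in the 19 staged tumours of the 3 genotypes that hold both, with genotype as a term, and the interaction of stage with p53 genotype was tested in the same tumours. Values per group are means with SD, and limma differences carry their SE.

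There were 27 gene lists for pathways and cell types, tested with camera at a preset correlation of 0.01 and adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it, and fry asks only whether a list's genes move on balance 1 way. The lists cover replication, mitosis, p53 targets, repair, Rb and ovarian cancer genes, epithelial, serous and surface epithelium markers, ciliated, granulosa, theca and luteal, oocyte, T and NK, B and plasma, macrophage, neutrophil, fibroblast, endothelial, smooth muscle, red blood and fat cells, interferon, MHC class I, mesenchymal transition, hypoxia and immediate early genes. Cell type lists describe the RNA of a sample, and no cell was classified. Groups, comparisons, tests, lists, most alternatives and the rule for named genes were fixed before the data were examined. A further 10 lists were chosen after the values were seen, and are named as such where used.

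The named genes are Brca1, Brca2, Rb1, Cdkn2a and Krt18, then per comparison the 10 largest rises and the 10 largest falls among called genes, leaving out clone and model names. Against normal epithelium only genes with all tumours on 1 side of all normal samples qualify for these. Up to 4 called members per list with the largest absolute difference follow. A comparison with under 5 calls names its calls and the 5 genes of smallest p. The text uses some of these, and says where a gene was chosen after its values were seen.

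Alternatives changed 1 choice at a time, except that the intensity trend and the robust prior of limma were changed together. They were quantile normalization again, arrays centred on their medians, the dimmest 40 percent of genes left out, the mean of a gene's probe sets, an intensity trend with a robust prior, array weights, at least 2-fold change, each replicate left out in turn in groups of 3 to 5, only the groups compared and the form of the animal number as a block. Further ones were all 27 tumours as 1 group, and for stage no genotype term or B1 fl/fl p53 fl/fl tumours only. Added after seeing the data were fits without the 4 arrays whose median correlation within their group is under 0.96, within a single form of animal number, and with the Gapdh 3′ minus 5′ control difference as a covariate. Other splits of the samples into groups of the same sizes were fitted in the same way, at most 100 per comparison.

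The calling was tested on simulated arrays, drawn from each gene's mean and residual spread, with known shifts added. Values were drawn independently, without the correlation between genes or the outlying arrays of the real data. Recovery and false calls in the real data may therefore be worse. At a log2 shift of 1 limma recovered 75% of shifted genes for tumours against normal epithelium, 74% for B1, 62% for p53, 58% for B2 against B1 and 75% for stage, and at a shift of 2 it recovered 95%, 97%, 93%, 87% and 98%. False calls numbered 4, 12, 10, 11 and 6 in the same order. All of 20 shifted lists were called by camera in each comparison, and of 20 lists left as they were 2 were called for p53 and 0 in the others. Shares of genes on a chromosome were compared by Fisher's exact test, two-sided. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the remaining work.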

Results

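RNA from 27 mouse ovarian tumours and 3 samples of normal ovarian surface epithelium was measured on 30 expression arrays, all from strain FVB/NJ. The labels write the tumour genotypes as combinations of B1 fl/fl or B2 fl/fl, K18 tg, and p53 fl/fl or p53 m/fl, and these names are used here as the labels give them. There were 14 tumours of genotype B1 fl/fl p53 fl/fl, 4 with K18 tg and p53 fl/fl but no B1 entry, 3 of B1 fl/fl p53 m/fl, 5 of B2 fl/fl p53 m/fl, and 1 labelled B1 fl/+, K18, cp. K18 tg is part of every replicated genotype, and the name alone is used below for the 4 tumours without a B1 or B2 entry. All values are log2 expression, array medians ran from 7.17 to 7.47, and the number of arrays limits the precision. The median correlation between arrays, computed across genes, which are not independent replicates, was 0.972 between tumours, 0.975 between normal samples and 0.921 between a tumour and a normal sample. Unless stated otherwise a gene is called different at an adjusted p under 0.05 in limma over 18193 genes.

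Genes fixed in advance for all groups came first. The labels do not spell out B1 and B2, and choosing Brca1 and Brca2 rests on an assumed reading of them. Brca1 (Entrez gene 12189) and Brca2 (12190), both needed for homologous recombination, were higher in all 27 tumours than in all 3 normal samples. Brca1 was 10.47 ± 0.40 (SD, n = 14) in B1 fl/fl p53 fl/fl tumours, 10.28 ± 0.47 (n = 4) in K18 tg p53 fl/fl, 9.69 ± 0.29 (n = 3) in B1 fl/fl p53 m/fl, 10.56 ± 0.33 (n = 5) in B2 fl/fl p53 m/fl and 7.93 ± 0.27 (n = 3) in normal epithelium. Tumours exceeded normal epithelium by 2.32 (SE 0.23, limma adjusted p = 1.57e-08), or 5-fold. For Brca2 the means were 10.37 ± 0.59, 10.31 ± 0.52, 9.68 ± 0.27, 10.45 ± 0.22 and 8.05 ± 0.44 in the same order, and the tumours were higher by 2.15 (SE 0.30, limma adjusted p = 3.26e-06). Between B1 fl/fl and K18 tg tumours with p53 fl/fl, Brca1 differed by 0.18 (SE 0.21, limma adjusted p = 0.979) and was not called. Where the probes of these genes lie relative to any deleted part is not given in the sources used here, so their signal does not check the deletion.

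Cdkn2a (Entrez gene 12578), which encodes the cell cycle inhibitor p16 and the p53 stabiliser p19ARF, had the largest fitted rise of the named genes. It was 10.73 ± 0.49 (SD, n = 14) in B1 fl/fl p53 fl/fl tumours, 10.60 ± 0.36 (n = 4) in K18 tg p53 fl/fl, 11.16 ± 0.26 (n = 3) in B1 fl/fl p53 m/fl, 10.89 ± 0.31 (n = 5) in B2 fl/fl p53 m/fl and 5.65 ± 0.15 (n = 3) in normal epithelium. The fitted difference was 5.19 (SE 0.25, limma adjusted p = 6.37e-15). The normal values lie near the arrays' lower quartiles (5.45 to 5.58) and detection calls were not used, so background limits this difference, and it is given as no exact fold. Krt18 (16668), a keratin of simple epithelia, was 1.38 higher in tumours (SE 0.10, limma adjusted p = 3.18e-11), with 13.67 ± 0.14 (n = 14) in B1 fl/fl p53 fl/fl tumours against 12.28 ± 0.33 (n = 3). Rb1 (19645) was 0.39 higher, which was not called (limma adjusted p = 0.122). The p53 gene itself was not analysed here.

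**Figure D1:**
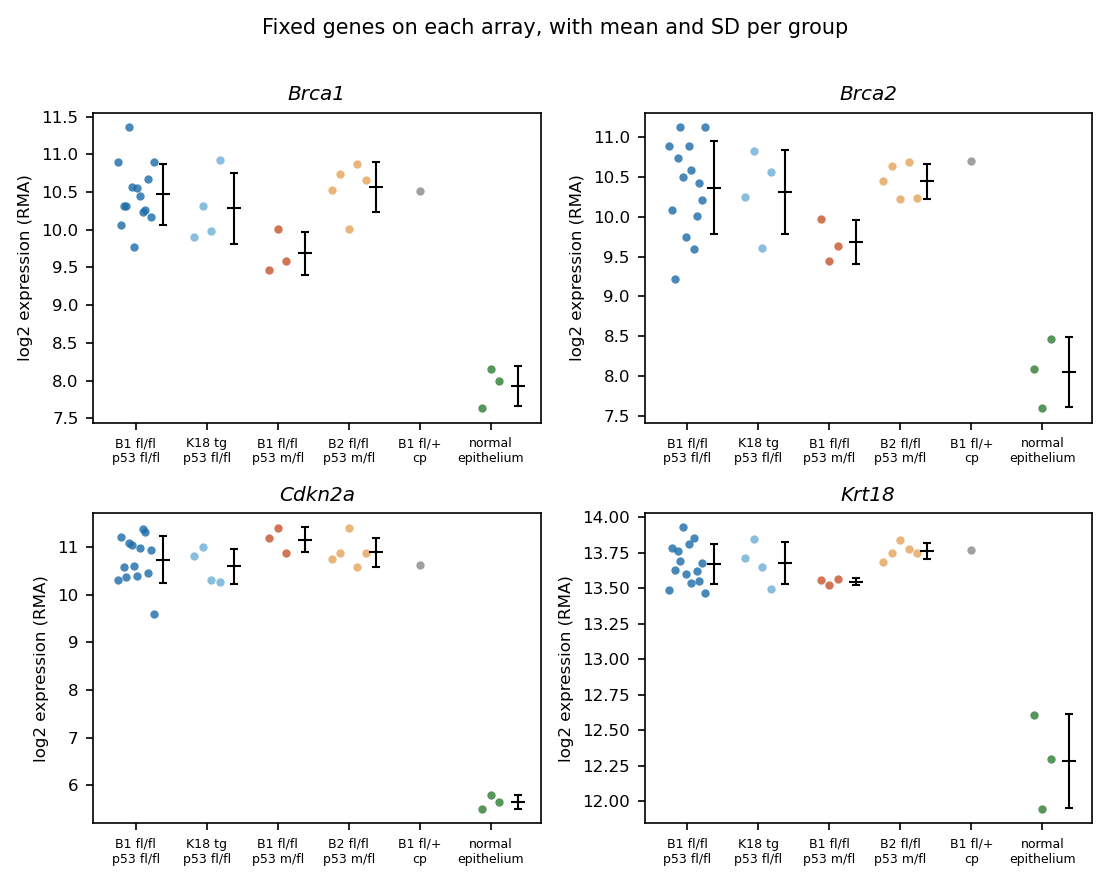
Log2 expression (RMA, vertical axis) of Brca1, Brca2, Cdkn2a and Krt18 on each of the 30 arrays, by tumour genotype and normal epithelium (horizontal axis), with points for arrays and bars for the mean and SD of each replicated group. All 27 tumours lie above the 3 normal samples in each panel, and mean Cdkn2a in normal epithelium was 5.65.

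Tumours were first compared with normal ovarian surface epithelium, as the equal-weight mean of the 4 replicated genotypes (26 tumours) against 3 normal samples. Genes of cell division rose together. All 29 measured genes of the mitosis list were higher, with a median log2 difference of 1.90 (camera adjusted p = 1.29e-25). That list call was lost with an estimated correlation (adjusted p = 0.0671). The 29 genes include the kinetochore motor Cenpe (3.37), the proliferation marker Mki67 (3.25), the spindle motor Kif11 (3.02) and the anaphase activator Cdc20 (2.83). The list's mean was 9.02 ± 0.39 (SD, n = 3) in normal epithelium and 10.99 ± 0.33 (n = 14) in B1 fl/fl p53 fl/fl tumours. Of 31 DNA replication and E2F target genes 28 were higher and 0 lower (median 1.31, camera adjusted p = 1.24e-22). They included the polymerase subunit Pole (3.68), the licensing factor Cdc6 (2.79), thymidine kinase Tk1 (2.33) and the helicase subunit Mcm6 (2.26). The replication call was kept with an estimated correlation (adjusted p = 0.0340).

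DNA repair genes of homologous recombination and the Fanconi pathway were mostly higher: 21 of 31 rose and 4 fell (median 0.98, camera adjusted p = 1.37e-07, and adjusted p = 0.115 with an estimated correlation). Rad54b rose by 2.62, the helicase Blm by 2.43 and the nuclease Exo1 by 2.41, while Fancc was at −2.39. The end joining and base excision repair list was not called (4 of 19 higher and 1 lower, median 0.03, adjusted p = 0.148), although the glycosylase Neil3 was 2.54 higher. In the list of Rb, cell cycle control and ovarian cancer genes 7 of 23 rose and 3 fell (median 0.21, camera adjusted p = 0.00955, and adjusted p = 0.0351 with an estimated correlation). Cdkn2a was at 5.19, Brca1 at 2.32 and cyclin D2, Ccnd2, at −3.25. Genes that p53 is known to induce showed no common shift: 3 of 26 were higher and 10 lower (median −0.24, adjusted p = 0.850). The cell death gene Pmaip1 was at 3.67, the epoxide hydrolase Ephx1 at −1.94 and Phlda3 at −1.50. The p21 gene Cdkn1a was 1.16 higher (limma adjusted p = 0.0111), and without normal sample 2 it was 0.61 and not called.

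Hypoxia and glycolysis genes rose, 12 of 15 with 0 lower (median 0.67, camera adjusted p = 5.22e-08, and adjusted p = 0.103 with an estimated correlation). Called members were the angiogenic factor Vegfa (2.81), Pdk1 (1.64) and hexokinase Hk2 (1.52). Of 17 interferon response genes 6 rose and 2 fell (median 0.78, camera adjusted p = 0.0175, and adjusted p = 0.595 with an estimated correlation). Oasl1 was at 3.17 and the chemokine Cxcl10 at 1.88. In MHC class I presentation 4 of 10 rose and 0 fell (median 0.34, camera adjusted p = 0.0234, and adjusted p = 0.595 with an estimated correlation). The class I transactivator Nlrc5 was at 3.23 and Tapbp at 0.61. Without normal sample 2 neither list was called, with medians of 0.58 for interferon and 0.28 for MHC class I. Immediate early and stress genes were not called (3 of 14 higher, 0 lower, median 0.17, adjusted p = 0.0955), and were called without normal sample 1 (median 0.46). The transcription factor Atf3 was 2.19 higher.

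Among epithelial junction and keratin genes 7 of 21 rose and 2 fell (median 0.25, camera adjusted p = 0.00422, and adjusted p = 0.592 with an estimated correlation). The keratins Krt7 (1.99), Krt8 (1.61) and Krt19 (1.39) rose. The splicing factor Esrp1 was lower by −2.40 (limma adjusted p = 0.0265), a call lost without any 1 of the normal samples (−2.43 to −2.33). It turned to 0.37 (limma adjusted p = 0.892) with the Gapdh 3′ minus 5′ control difference as a covariate. Markers of ovarian surface epithelium showed no call as a list (4 of 20 higher, 2 lower, median 0.17, adjusted p = 0.224), but the stem cell marker Lgr5 was 2.87 higher (limma adjusted p = 0.00521). Serous and Müllerian tumour markers were not called (0 of 18 higher, 3 lower, median −0.15, adjusted p = 0.850), with Hoxa7 at −0.79. Nor were ciliated cell markers (2 of 14 higher, 2 lower, median 0.02, adjusted p = 0.708). Of the mesenchymal transition genes 1 of 16 was higher and 8 lower (median −0.77, adjusted p = 0.148). S100a4 was at −3.41, Twist2 at −2.75 and Snai1 at −1.97.

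Transcripts of other ovarian cell types were higher in the normal epithelium than in tumours. Of 14 oocyte genes 12 were lower in tumours and 0 higher (median −3.56, camera adjusted p = 2.00e-19, and adjusted p = 0.000367 with an estimated correlation). Called members were the zona pellucida genes Zp2 (−5.41) and Zp3 (−4.80), Nlrp5 (−5.06) and the oocyte transcription factor Nobox (−5.01). The mean of the oocyte list was 9.75 ± 0.47 (SD, n = 3) in normal epithelium, and from 6.05 to 6.38 in the replicated tumour groups. Of 8 theca, luteal and steroidogenic genes 7 were lower and 0 higher (median −4.06, camera adjusted p = 0.000144, and adjusted p = 0.0848 with an estimated correlation). The steroid dehydrogenase Hsd3b1 was at −6.83, the prostaglandin receptor Ptgfr at −6.71, Cyp17a1 at −5.32 and Akr1c18 at −5.29. With the Gapdh 3′ minus 5′ control difference as a covariate, a fit added after seeing the data, the list median was −1.61 with 2 genes called, and Akr1c18 was 0.86 (limma adjusted p = 0.749). Of 12 granulosa cell genes 8 were lower and 1 higher (median −1.60, camera adjusted p = 0.0181, and adjusted p = 0.276 with an estimated correlation). Inhba was at −3.68, Hsd17b1 at −3.34 and the granulosa factor Foxl2 at −2.91.

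Endothelial and T and NK cell genes were lower in tumours. Of 15 endothelial genes 7 fell and 0 rose (median −0.92, camera adjusted p = 0.0229, and adjusted p = 0.595 with an estimated correlation). The tight junction gene Cldn5 was at −2.34, Eng at −1.88 and the receptor Tek at −1.43. Of 17 T and NK cell genes 11 fell and 2 rose (median −0.66, camera adjusted p = 0.0391, and adjusted p = 0.592 with an estimated correlation). Thy1 was at −1.87, the T cell receptor subunits Cd3g at −1.82 and Cd3d at −1.54, and Nkg7 at −1.66. Without normal sample 1 neither list was called (medians −0.71 and −0.41), nor was the T and NK list without the arrays of low correlation (−0.67). With the dimmest 40 percent of genes left out the T and NK list turned and was called higher in tumours (median 1.34, camera adjusted p = 0.0423). Fibroblast and matrix genes were not called as a list (8 of 17 lower, 1 higher, mean −1.17, adjusted p = 0.234), although the matrix genes Lum (−5.17) and Col1a2 (−3.55) and the receptor Pdgfrb (−2.25) were each lower. Smooth muscle (4 of 10 lower, 0 higher, median −0.79, adjusted p = 0.224), with the myosin Myh11 at −2.68, was not called either.

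The remaining lists showed no call. These were macrophages and dendritic cells (2 of 20 higher, 3 lower, median −0.20, adjusted p = 0.850) and neutrophils (0 of 12 higher, 1 lower, median 0.22, adjusted p = 0.387). They also include B and plasma cells (0 of 10 higher, 1 lower, median −0.10, adjusted p = 0.850), red blood cells (0 of 5 higher, 1 lower, median 0.27, adjusted p = 0.743), and adipocytes (0 of 8 higher, 1 lower, median −0.35, adjusted p = 0.812). Camera's direction for the macrophage list was up, opposite to its median and its mean of −0.20. Adjusted over the list alone, the counts of most lists were the same as over all genes. They differed for p53 targets (4 higher), homologous recombination (5 lower), end joining (0 lower), serous markers (2 lower), surface epithelium (3 higher) and B and plasma cells (0 lower). They also differed for macrophages (1 higher), neutrophils (0 lower), endothelial cells (8 lower), interferon (7 higher), mesenchymal transition (9 lower) and immediate early genes (2 higher).

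**Figure D2:**
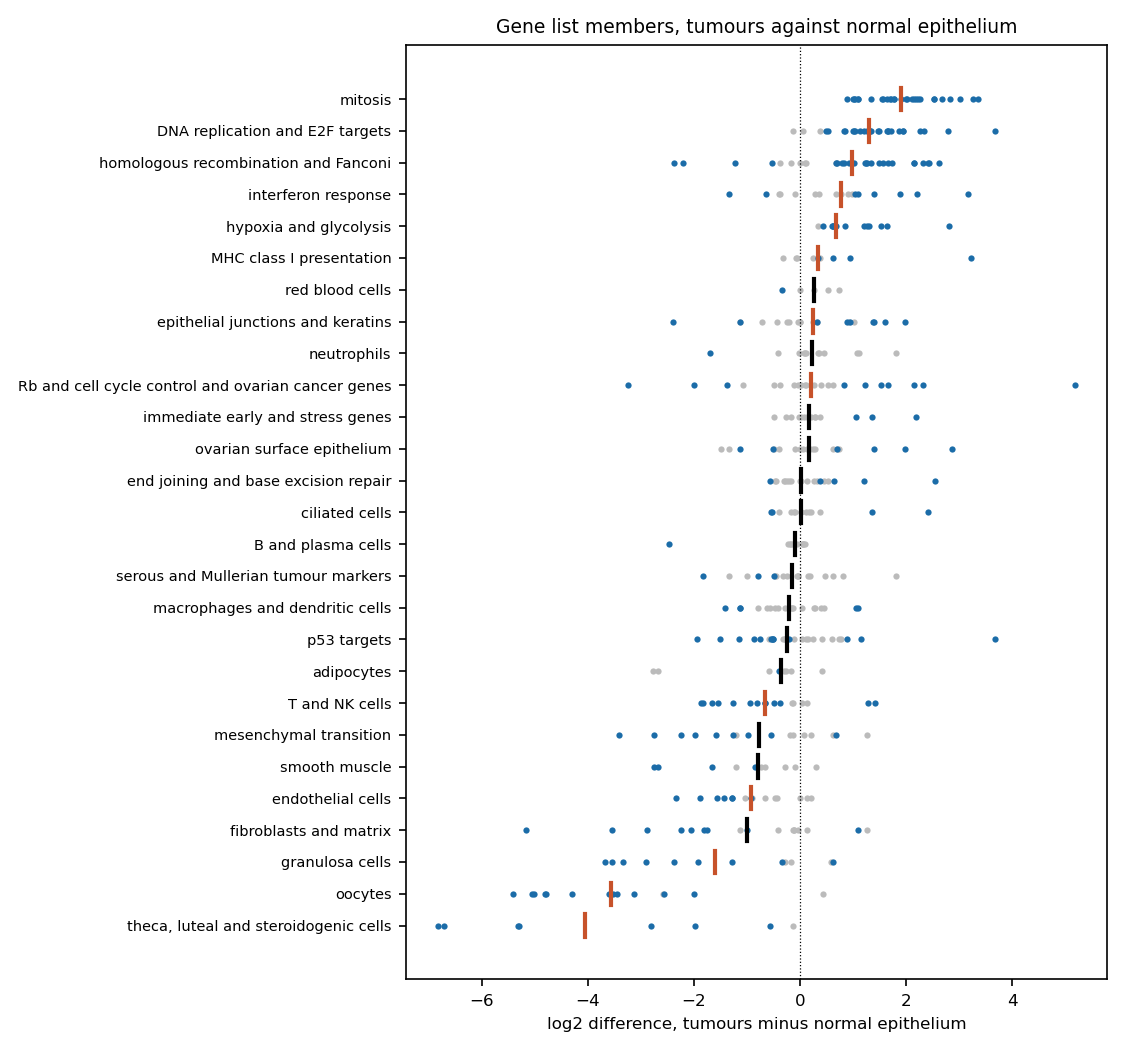
Log2 difference between tumours and normal epithelium (horizontal axis) for each measured member of the 27 gene lists (vertical axis), with blue points for members called by limma, grey points for the others, and a bar at the list's median, orange where the list passed camera. The median was 1.90 for mitosis, −3.56 for oocytes and −4.06 for theca, luteal and steroidogenic cells.

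Of the single genes whose tumours all lay on 1 side of all normal samples, those with the largest fitted rise after Cdkn2a were the noncoding RNA Lockd (4.90, SE 0.35, limma adjusted p = 2.27e-11), Pnliprp2 (4.62) and Tmem88b (4.30). Next came the nuclear paraspeckle RNA Neat1 (4.17, SE 0.48, limma adjusted p = 1.50e-07), Slc16a4 (4.07), the mitotic spindle gene Spag5 (4.05), Synpr (3.83), Crybg1 (3.73) and the noncoding RNA Firre (3.71). Another probe set of Slc16a4 was called in the opposite direction, at −0.95. The largest fitted falls were those of the peroxisomal oxidase Hao2 (−7.43, SE 0.51, limma adjusted p = 1.35e-11), Hsd3b1, Ptgfr, the matrix gene Ogn (−6.13) and the germ cell gene Mael (−5.85). They were followed by Slc26a7 (−5.85), Mmrn1 (−5.82), the ephrin receptor Epha3 (−5.75), Mkx (−5.44) and Zp2. Mean log2 expression in the 27 tumours was 4.05 for Hao2, 3.62 for Mael and 4.19 for Zp2, below every array's lower quartile, so background limits these differences and their order. For Mael the SD among normal samples was 0.93, wider than its SE of 0.17, since limma pools the spread over all groups.

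In all 7559 of 18193 genes were called, 2718 higher and 4841 lower, and 2578 of them differed at least 2-fold (1198 higher, 1380 lower). With the dimmest 40 percent of genes left out 2477 were higher and 2166 lower, so the excess of falls was not kept. All 27 tumours lay above all normal samples for 923 genes and below them for 1487, where chance gives 0.0246% of genes in each direction. The median over all genes was −0.11, and quantile normalization moved it by 0.13, with 50.3% of the calls then higher, against 36.0% before. Small differences such as the medians of the epithelial and Rb lists are to be set against that shift. Of the 3905 called genes with other probe sets, 313 had one called in the opposite direction. Laser capture and a different RNA kit went with the normal samples and cannot be told apart from the tissue. The 3′ minus 5′ Gapdh control difference, a measure of RNA shortening, was 1.84, 1.37 and 1.39 in the normal samples and from 0.70 to 1.28 in tumours. With it as a covariate 4013 genes were called, 3175 of them among the 7559. The same difference for the actin control was 1.83, 1.41 and 1.33 in the normal samples and from 0.88 to 1.66 in tumours. For actin, normal samples 2 and 3 thus lay within the range of the tumours.

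Each tumour genotype was also set against the same 3 normal samples. By limma 7179 genes were called for B1 fl/fl p53 fl/fl (2661 higher, 4518 lower), 6327 for K18 tg p53 fl/fl (2195 higher, 4132 lower), 4679 for B1 fl/fl p53 m/fl (1835 higher, 2844 lower) and 6456 for B2 fl/fl p53 m/fl (2337 higher, 4119 lower). Without replicate 1 of B1 fl/fl p53 m/fl its lower genes numbered 1894. After quantile normalization an excess of falls was kept only for K18 tg p53 fl/fl, where it was smaller. The counts were then 3286 higher and 3256 lower, 2467 and 2634, 2137 and 1925, and 2842 and 2799 in the same order. The mean of the mitosis list lay between 10.79 and 11.05 in the replicated tumour groups, and that of the oocyte list between 6.05 and 6.38. The controls are shared, so the overlap of these calls was not tested, and the groups differ in size.

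The labels of B1 fl/fl p53 fl/fl (n = 14) and K18 tg p53 fl/fl tumours (n = 4) differ only in B1, which makes this the comparison for B1 fl/fl. Several cell type lists were called lower in the B1 fl/fl tumours by camera with its preset correlation, and none of these calls held with an estimated correlation. The lists were adipocytes (median −1.42, adjusted p = 5.42e-07), B and plasma cells (−0.32, 5.42e-07), smooth muscle (−0.65, 6.11e-07), fibroblasts and matrix (−0.46, 1.45e-06) and ovarian surface epithelium (−0.28, 2.61e-06). With an estimated correlation the adjusted p was 0.116 for the first 3, 0.226 for fibroblasts and 0.164 for surface epithelium. Smaller falls were called for MHC class I (−0.25, adjusted p = 0.000275), mesenchymal transition (−0.37, adjusted p = 0.00111), interferon response (−0.20, adjusted p = 0.0147) and neutrophils (−0.32, adjusted p = 0.0299). Hypoxia genes (0.22, adjusted p = 0.00120) and mitosis (0.19, adjusted p = 0.00584) were called higher. With an estimated correlation these 6 had an adjusted p of 0.450, 0.342, 0.772, 0.792, 0.493 and 0.792, so that none of the 11 calls held, and fry called 0 lists. Endothelial, macrophage, T and NK and red blood cell lists were not called. Adjusted over the list alone, 3 of 10 B and plasma cell genes and 3 of 8 adipocyte genes were lower.

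Among the 4 K18 tg tumours the high stromal values were those of replicates 3 and 4, whose animal numbers carry an R prefix. The mean of the adipocyte list was 7.24 and 7.67 in replicates 1 and 2 and 11.4 and 10.2 in replicates 3 and 4, against 7.92 ± 0.64 (SD, n = 14) in B1 fl/fl tumours. For fibroblasts these means were 9.56, 9.61, 11.6 and 10.8 against 9.77 ± 0.66, for smooth muscle 8.45, 8.28, 9.73 and 10.4 against 8.48 ± 0.48, and for B and plasma cells 5.43, 5.54, 6.56 and 7.03 against 5.55 ± 0.20. Within tumours with the R prefix the medians were −3.31 for adipocytes, −1.48 for fibroblasts, −1.55 for smooth muscle and −0.76 for B and plasma cells. Within tumours with six-digit numbers these medians were 0.35, 0.49, 0.38 and 0.091. Those of neutrophils (0.52), mesenchymal transition (0.083) and mitosis (−0.077) were also on the other side of 0. The medians of mitosis (−0.013) and neutrophils (0.24) turned without K18 tg replicate 3. Without it adipocytes (−0.44), fibroblasts (−0.11) and mesenchymal transition (−0.08) were no longer called. That of interferon (0.15) turned without replicate 1.

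**Figure D3:**
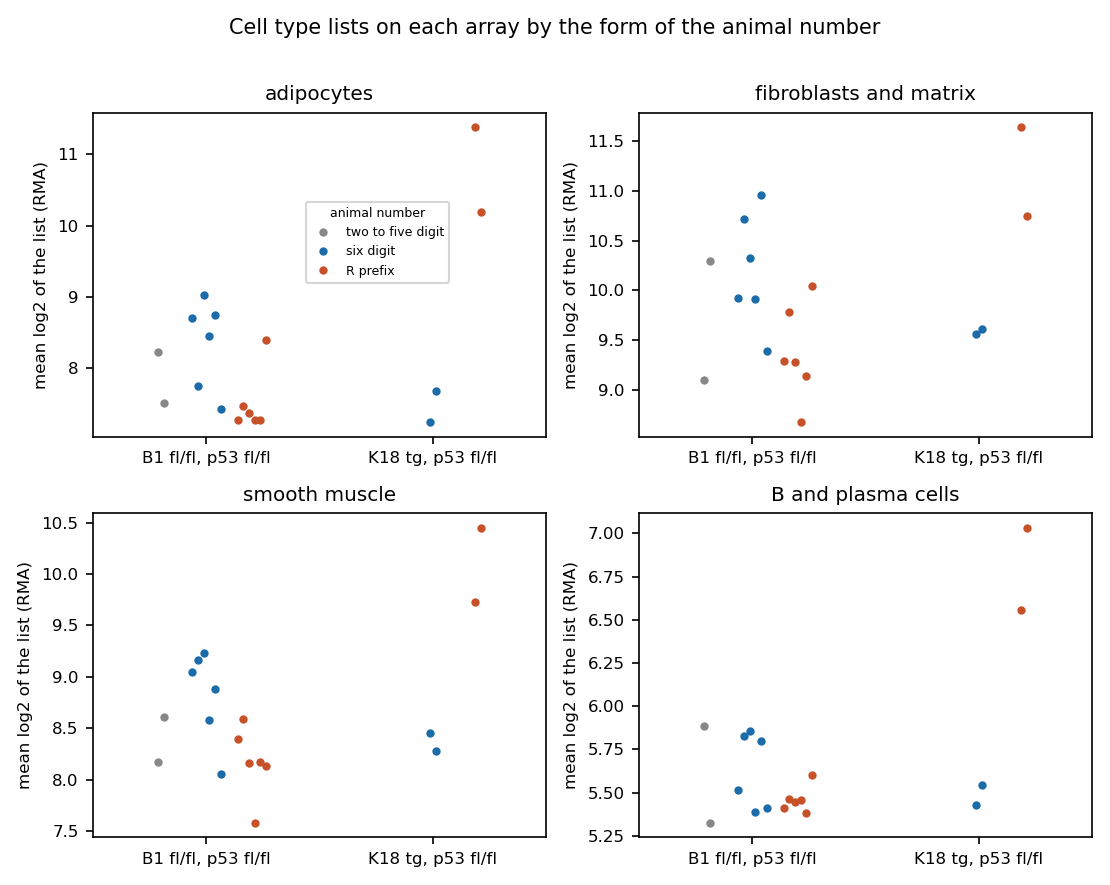
Mean log2 expression (RMA, vertical axis) of the adipocyte, fibroblast, smooth muscle and plasma cell lists in the 14 B1 fl/fl and 4 K18 tg tumours with p53 fl/fl (horizontal axis), a point per tumour, coloured by the form of the animal number. K18 tg replicates 3 and 4, with the R prefix, had adipocyte means of 11.4 and 10.2, and replicates 1 and 2, with six-digit numbers, 7.24 and 7.67.

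No single gene was called between these genotypes. In limma 0 of 18193 genes passed, with 767 at an unadjusted p under 0.05 where 909.7 are expected by chance. The 5 genes with the smallest p, none passing, were the interferon-inducible Mndal (−1.29, SE 0.26, limma adjusted p = 0.279), D730045A05Rik (0.34), the mucin-like Glycam1 (−0.72), Gm16316 (−2.60) and the mast cell protease Mcpt4 (−0.78). Brca2 differed by 0.06, Rb1 by 0.19, Cdkn2a by 0.14 and Krt18 by −0.00. With the form of the animal number as a block limma called 0 genes, within six-digit tumours 2 and within R prefix tumours 99. Without K18 tg replicate 1 there were 12 calls, and without replicate 3 or 4 there was 1.

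B1 fl/fl p53 m/fl tumours (n = 3) were compared with B1 fl/fl p53 fl/fl tumours (n = 14) for the effect of the p53 genotype. Host genes of small nucleolar RNAs were among the falls: Snhg3 by −1.84 (SE 0.39, limma adjusted p = 0.0455), Snhg5 by −1.31 (SE 0.26, limma adjusted p = 0.0314) and, chosen after its values were seen, Gas5 by −1.05 (SE 0.16, limma adjusted p = 0.0110). Snhg5 was 10.55 ± 0.55 (SD, n = 3) in p53 m/fl tumours and 11.85 ± 0.31 (n = 14) in p53 fl/fl tumours. Other falls were those of the glycolysis regulator Pfkfb2 (−1.38, SE 0.23, limma adjusted p = 0.0110), the microtubule-associated ligase Mid1 (−1.66), the mitochondrial import gene Timm10b (−1.20), Paxbp1 (−1.35), Zc3h7a (−1.32), Trim6 (−1.27), Zfp995 (−1.26) and Pram1 (−1.19). Higher in p53 m/fl tumours were Slfn8 of the Schlafen family (2.02, SE 0.37, limma adjusted p = 0.0183), the muscle actinin Actn3 (1.71), the delta tubulin Tubd1 (1.60, SE 0.27, limma adjusted p = 0.0110), the chemokine Cxcl9 (1.54), Gnpda1 (1.30), the sodium channel subunit Scnn1a (1.28), Pnoc (1.27), Galnt10 (1.02), Morn5 (1.01) and Mogat2 (0.98). Without replicate 1 of the p53 m/fl tumours Scnn1a was 0.75, Zfp995 −0.71 and Cxcl9 1.00, and without replicate 2 Pnoc was 0.83, none of them called. Other named genes lost their calls too, Mid1 and Galnt10 without any 1 of the 3 replicates. Of all 47 genes called in this comparison 3 stayed called without replicate 1, 13 without replicate 2 and 21 without replicate 3. Gnpda1 was 9.59 ± 1.04 (SD, n = 3) in p53 m/fl against 8.29 ± 0.34 (n = 14) in p53 fl/fl tumours. Of the rises named here Slfn8, Tubd1 and Galnt10 lie on the chromosome of Brca1, and none of the named falls does.

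In total 47 genes were called, 17 higher and 30 lower, 27 of them at least 2-fold, with 2153 at an unadjusted p under 0.05. No list was called by camera, with a preset or an estimated correlation, or by fry, and this includes the 26 p53 targets. Brca1 differed by −0.78 (SE 0.24, limma adjusted p = 0.171), Brca2 by −0.68 (limma adjusted p = 0.382) and Cdkn2a by 0.42 (limma adjusted p = 0.549), none called. All p53 m/fl tumours have animal numbers of 2 to 5 digits, as only replicates 1 and 2 of the p53 fl/fl tumours do. With that form as a block limma called 0 genes, and within it, 3 tumours against 2, 0 genes. The median difference of the 47 genes, in their direction, was 1.04 within it against 1.05 in the comparison. The calls thus ended without a smaller median difference, but the genes were selected on the same p53 m/fl tumours, which favours a large one. Without replicate 1 of the p53 m/fl tumours there were 4 calls, without replicate 2 there were 22, and 51 without replicate 3, of which 21 were among the 47. The share of calls that were higher changed with the setting. It was 36.2%, 47.1% of 34 after quantile normalization, 50.0% of 22 after centring, 20.0% of 50 with the dimmest genes left out and 63.2% of 19 with the mean of probe sets. It was 4.55% without replicate 2 and 64.7% without replicate 3.

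**Figure D4:**
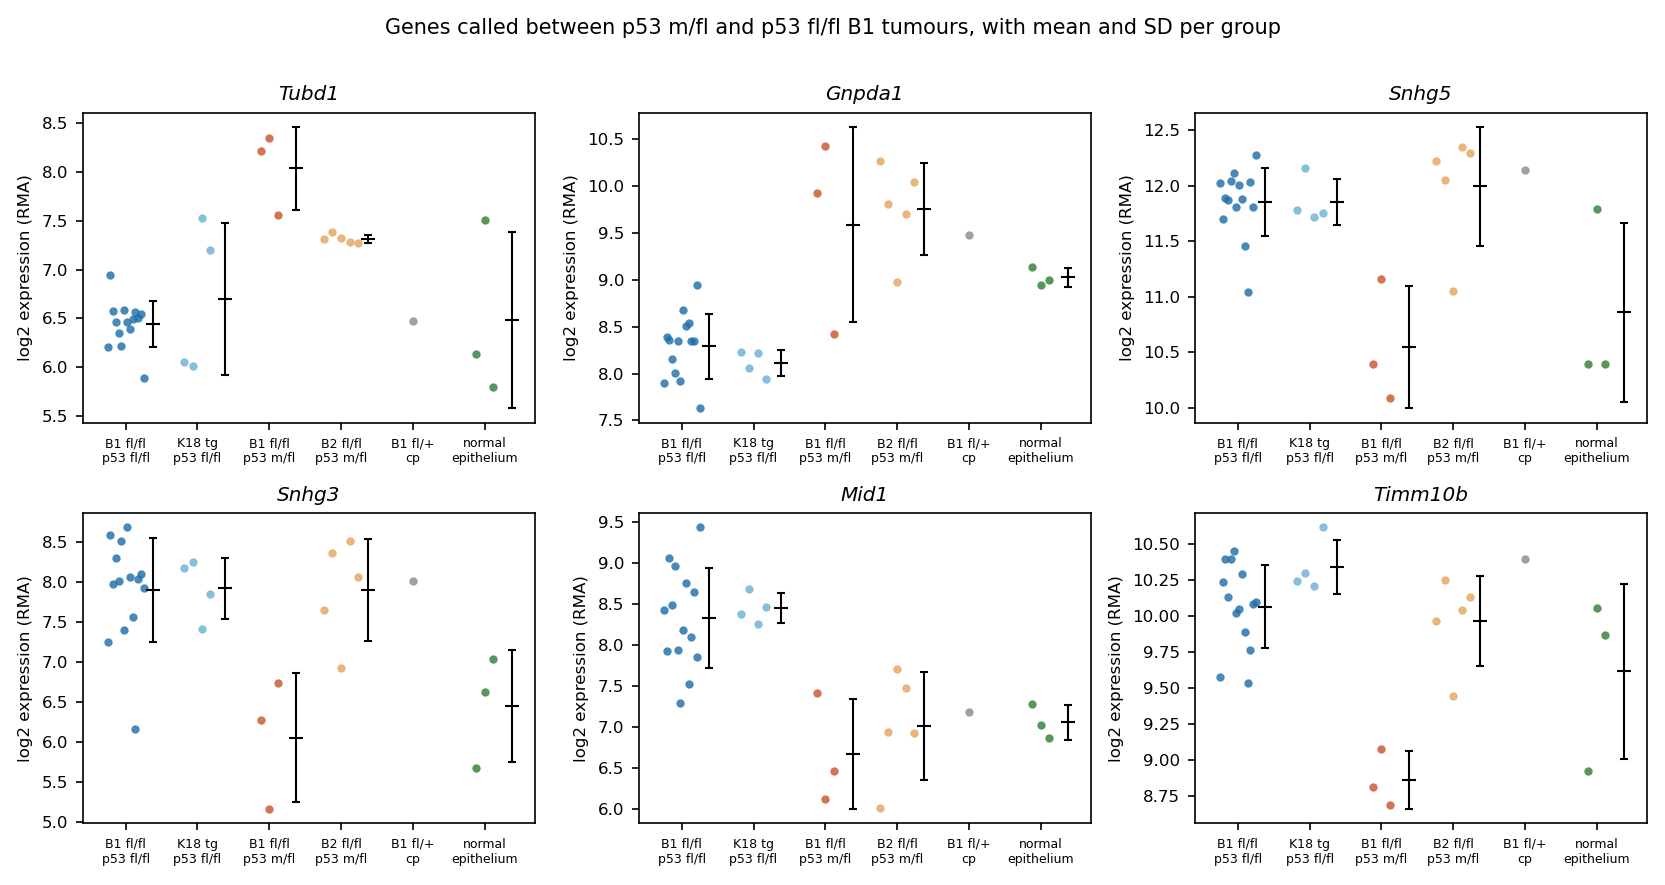
Log2 expression (RMA, vertical axis) of 6 genes called between B1 fl/fl tumours with p53 m/fl and p53 fl/fl on each of the 30 arrays, by group (horizontal axis), with points for arrays and bars for the mean and SD. Snhg5 was 10.55 in B1 fl/fl p53 m/fl and 11.99 in B2 fl/fl p53 m/fl tumours, while Mid1 was 6.67 and 7.01 in these groups.

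Tumours with B2 fl/fl (n = 5) and B1 fl/fl (n = 3), all p53 m/fl, differed in 1 gene: Zfyve27, which encodes protrudin, was 1.11 higher with B2 fl/fl (SE 0.18, limma adjusted p = 0.0231), and 1385 genes had an unadjusted p under 0.05. Its other probe sets gave 0.88, 0.50 and −0.02 and were not called. The next genes by p, none passing, were the coactivator Ncoa7 (2.24), the growth factor Fgf1 (1.43), the phosphatase Dusp11 (0.61) and Gas5 (0.96), each with a limma adjusted p of 0.0768. Brca1 was 0.87 higher with B2 fl/fl (limma adjusted p = 0.404) and Brca2 0.76 (limma adjusted p = 0.637), neither called, and no list was called by camera or fry. The count rests on single arrays. Without B2 fl/fl replicate 3 it was 22, without its replicate 1 it was 4 and without its replicate 2 or 4 it was 2. Without B1 fl/fl replicate 3 it was 16, and without B1 fl/fl replicate 2 or B2 fl/fl replicate 5 it was 0, with Zfyve27 at 1.02 in both. Without the 4 arrays of low correlation within their group 91 genes were called.

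Stage was compared in 19 tumours of the B1 fl/fl p53 fl/fl, B1 fl/fl p53 m/fl and B2 fl/fl p53 m/fl genotypes, 11 of stage IV and 8 of lower stage, with genotype in the model. Interferon response genes (median 0.31, camera adjusted p = 9.37e-06) and MHC class I genes (0.30, 0.000253) were called higher as lists in stage IV, as were hypoxia (adjusted p = 0.00114), homologous recombination (adjusted p = 0.0154) and endothelial genes (adjusted p = 0.0434), while epithelial junction and keratin genes were called lower (−0.28, 0.00445). With an estimated correlation the adjusted p of these 6 lists ran from 0.635 to 0.748, and fry called 0. In limma 0 genes were called, with 554 at an unadjusted p under 0.05 and 909.7 expected. The smallest p values, none passing (limma adjusted p = 1.00), belonged to Impact (0.57), Ciao2a (−0.33), S100a3 (−0.71), Rufy2 (0.38) and Prss32 (−0.33). In B1 fl/fl p53 fl/fl tumours only, 11 of the 19, the median of homologous recombination turned to −0.044. Leaving out B1 fl/fl p53 m/fl replicate 1 ended the calls of endothelial (0.07) and homologous recombination genes (0.12). The latter call also ended without B2 fl/fl replicate 2 (0.07), 3 (0.05) or 4 (0.09), and the endothelial call without B1 fl/fl p53 m/fl replicate 2 (0.16) or B2 fl/fl replicate 5 (0.21). Whether the stage difference itself differs between p53 fl/fl and p53 m/fl tumours was tested as an interaction. Limma called 0 genes, with 1181 at an unadjusted p under 0.05, and 12 lists were called by camera, 0 with an estimated correlation or by fry.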

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

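Chosen only after the results were seen were the Gapdh test of theca and luteal genes, the test of the B1 genotype within six-digit tumours, the lists of further oocyte and further fat cell transcripts, and the fits within a form of animal number or with the Gapdh covariate.

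The first pattern is the high level of oocyte, theca and luteal transcripts in the laser-captured normal epithelium. RNA of neighbouring oocytes is a candidate source: 20 of 22 further oocyte transcripts were lower in tumours and 0 higher. Their median log2 difference was −1.42, below that of all 10000 random lists of like expression, and they were led by Nlrp14 (−5.25), Nlrp4f (−4.81) and Lhx8 (−4.25). Nlrp4f was 5.25 to 5.39 in B2 fl/fl tumours other than replicate 3, below every array's lower quartile. Background thus limits its difference and this order. Capture by laser would leave such cells out, yet Zp2 stood at 9.60 ± 0.10 (SD, n = 3) in the normal samples. Shorter RNA in the captured samples stays open for both sets of genes. With the Gapdh control difference as a covariate the oocyte median was −3.96, against −3.56 without it. The theca and luteal median went from −4.06 to −1.61 with that covariate, and 2 genes instead of 7 were called. The median SE of the single theca and luteal genes rose from 0.52 to 0.94. The control difference was 1.37 to 1.84 in the normal samples and 0.70 to 1.28 in tumours. As these ranges do not overlap, the fit extrapolates and cannot decide. For the actin control the ranges overlapped, with 1.33 to 1.83 in the normal samples and 0.88 to 1.66 in tumours. The tissue itself stays open too, as capture, RNA kit and normal group coincide, so that the falls of these lists are not read as losses in tumour cells.

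The second pattern is the 47 genes called between B1 fl/fl p53 m/fl and p53 fl/fl tumours. B2 fl/fl p53 m/fl minus K18 tg p53 fl/fl tumours have the same p53 contrast. The genes shifted there in their direction by a median of 0.141 against 1.05 (0.0782 to 0.226 without any 1 array), and 2 of 47 passed over the list alone (Gnpda1 1.65, Mid1 −1.43). These values argue against a p53 effect on the whole set that has a like size whatever the B gene. Selection of the 47 genes favours a large value of 1.05, and the B gene differs between these tumours too. A p53 effect that depends on the B gene therefore stays open. For a smaller part of the set the p53 genotype stays open as well, since 0.141 lies above all random gene sets (upper limit 0.0656) and 33 of 47 genes lay in the same direction. The pair of p53 fl/fl tumours that share the form of the animal number shifted from the others by −0.0116. This pair was in the p53 fl/fl group when the 47 genes were selected. Such a selection favours genes that do not move in the pair, so the form of the animal number stays open. A chromosome segment carried along with the targeted alleles is argued against as the source of most, since 41 of 46 lie elsewhere than on the chromosome of Brca1. The share on it was 10.9% against 7.995% of the other genes (Fisher's exact p = 0.414). It stays open for the 5 on it: Slfn8, Tubd1, Galnt10 and Acsf2, higher, and Spag9, lower. A set of 7 genes was called between the mean of both p53 m/fl groups and that of the B1 fl/fl and K18 tg p53 fl/fl tumours. Of these 6 lie elsewhere, and 7 genes are too few for their share on it (14.3%, Fisher's exact p = 0.442) to decide. No B2 fl/fl p53 fl/fl tumours were measured, so the B gene differs there too. Of 100 splits of the B1 fl/fl p53 m/fl and p53 fl/fl tumours 7 gave as many genes as the real 47. The highest other gave 1516, so chance cannot be excluded.

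The third pattern is the set of stromal, fat, smooth muscle and plasma cell lists lower in B1 fl/fl than in K18 tg tumours. In tumours with six-digit numbers, only 2 of them K18 tg, fibroblast, adipocyte and smooth muscle means were higher in B1 fl/fl by 0.62, 0.89 and 0.46 (SE 0.24, 0.34 and 0.20). In tumours with the R prefix the medians of these lists were lower in B1 fl/fl (−1.48, −3.31 and −1.55). The falls were thus not common to both forms of animal number. The six-digit subset was chosen after the results were seen, so the B1 genotype as a cause stays open. For plasma cells, where it stays open too, the six-digit difference was 0.145 with an SE of 0.11. Fat and other non-tumour tissue in K18 tg replicates 3 and 4 is a candidate explanation: 19 of 23 further fat cell transcripts were higher in them than in replicates 1 and 2, with a median of 1.19 against an upper limit of 0.0960 for random lists. Adipoq was 12.1 in those replicates, 4.58 in the other two and 5.48 ± 1.65 in B1 fl/fl tumours, and Fabp4 12.8, 6.57 and 8.15 ± 2.87. Where each tumour grew and how it was dissected are not given in the sources used here, so tissue and animal series stay open.

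Other splits of the samples were counted for each comparison, with the real one included. For tumours against normal epithelium 1 of 100 splits gave as many genes as the real 7559 (highest other 1537), a share under 0.05. For lists 7 of 100 gave as many as the real 13 (highest other 15), a share above it. The share was also under 0.05 for the genes of B1 fl/fl p53 fl/fl tumours (1 of 100, real 7179, highest other 2077), K18 tg p53 fl/fl tumours (1 of 35, real 6327, highest other 3172) and B2 fl/fl p53 m/fl tumours (1 of 56, real 6456, highest other 2731) against normal epithelium. These shares were not adjusted over the comparisons. All rest on the same normal samples, which may not come from separate animals, so they do not exclude chance. For B1 fl/fl p53 m/fl tumours against normal epithelium there are only 10 splits, too few for a share under 0.05 (real 4679, highest other 43). Chance cannot be excluded for the B1 comparison (genes 100 of 100, real 0, highest other 577, and lists 32 of 100, real 11, highest other 18), for B2 against B1 (14 of 56, real 1, highest other 63), for stage (genes 100 of 100, real 0, highest other 39, and lists 55 of 100, real 6, highest other 14) or for the interaction (100 of 100, real 0, highest other 15). Where the real count is 0 every split gives as many, so these shares of 100 of 100 decide nothing. The splits with 577, 1516 and 63 genes were each the highest of their comparison, where the median of the other splits was 0. Each includes at least 1 array of low correlation with its own group, and no structure of the samples was tested. The split with 577 sets B1 fl/fl replicates 1, 3, 5 and 14 apart, and that with 1516 replicates 1, 13 and 14. That with 63 sets B2 fl/fl replicates 1 and 3 apart with B1 fl/fl p53 m/fl replicate 2.

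Single samples far from the others of their group were looked for in 320 groups of values, of the K18 tg p53 fl/fl (n = 4) and B2 fl/fl p53 m/fl tumours (n = 5), and 37 were found (11.6%), where chance gives about 1 in 20, or 16. Of these 20 belong to B2 fl/fl replicate 3, whose median correlation within its group was 0.946. It was lowest in log2 expression for Cdc6 (8.90), Rad54b (9.19), Pmaip1 (8.97), Krt19 (12.80), Lgr5 (6.44), Tmem88b (7.44), Slc16a4 (9.84), Snhg5 (11.05), Zfp995 (9.50), Dusp11 (11.08), Tet2 (10.24), Ezh2 (10.79), Dnmt3b (7.10), Rnf43 (7.12), Axin2 (10.22) and the mean of the replication list (10.64), and highest for Snai1 (5.47), Cyp17a1 (7.90), Pdgfrb (9.33) and Nlrp4f (5.85). B2 fl/fl replicate 1 was highest for Adipoq (9.94), Fabp4 (11.75), Cidec (7.78), Mogat2 (7.16) and the mean of the adipocyte list (9.36). B2 fl/fl replicate 2 was lowest for Hoxd8 (7.94) and the mean of the immediate early list (8.84). Among K18 tg tumours replicate 1 was lowest for Glycam1 (5.34), replicate 2 was lowest for Tapbp (12.93) and the mean of the immediate early list (8.98) and highest for Snhg5 (12.16), replicate 3 was lowest for Atf3 (8.50), Hao2 (3.498) and Trim6 (8.99) and highest for the mean of the neutrophil list (8.66), and replicate 4 was lowest for Pram1 (8.22) and highest for Mmrn1 (6.95).

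Camera's interaction test of stage with p53 genotype called 12 lists at its preset correlation, of which none was kept with an estimated correlation (adjusted p = 0.596 for mitosis and 0.535 for the other 11) or by fry. Values are the median log2 stage difference in p53 m/fl minus that in p53 fl/fl. It was positive for replication (0.29, camera adjusted p = 3.41e-05), mitosis (0.36, 4.38e-05), homologous recombination (0.42, 0.000290) and epithelial junctions and keratins (0.44, 0.00470). It was negative for macrophages (−0.90, 0.000149), neutrophils (−0.93, 0.00290), fibroblasts (−0.50, 0.00727), smooth muscle (−0.92, 0.00155), adipocytes (−0.42, 0.00287), mesenchymal transition (−0.37, 0.00421), hypoxia (−0.45, 0.000498) and immediate early genes (−0.66, 0.000164). Of the 8 p53 m/fl tumours 3 are of stage IV.

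The tumour labelled B1 fl/+, K18, cp enters no comparison, and its log2 values lie above the highest normal sample for Brca1 (10.51 against 8.15), Brca2 (10.70 against 8.46), Cdkn2a (10.62 against 5.81), Krt18 (13.77 against 12.61), the mean of the replication list (11.11 against 9.88) and that of the mitosis list (11.05 against 9.30).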

How the results depend on the processing

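Chosen only after the data were seen were the fits without arrays of low correlation, within a form of animal number, and with the Gapdh covariate. Counting each of the 110 genes named for tumours against normal epithelium once under each alternative fixed in advance, direction and side of the threshold were kept in 2294 cases, 89 calls were lost, 1 was gained and none reversed. Its 27 lists, counted in the same way, kept both in 559 cases, with 24 calls lost, 9 gained and 1 median reversed. The genes named for p53 kept both in 161 cases, with 105 calls lost and 1 gained. Where calls fell with fewer samples fitted, the lower power is in the alternative itself, and with fewer genes fitted fewer can be called. For all other changes below the cause was not tested. Probe sets with dim signal limit what the arrays resolve, since detection calls were not used here.

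For tumours against normal epithelium 4643 genes were called with the dimmest 40 percent left out, 2578 at least 2-fold and 4013 with the Gapdh covariate, and 3 lists with an estimated correlation. Per genotype (B1 fl/fl p53 fl/fl, K18 tg, B1 fl/fl p53 m/fl, B2 fl/fl) these were 4675, 3666, 2872 and 3872 with the dimmest genes left out and 2642, 2526, 2202 and 2591 at least 2-fold, and array weights gave 9550, 7491 and 10099 for the last 3. For B1 there was 1 gene with the mean of probe sets, 1 with array weights, 1 with only the groups compared, 2 within six-digit and 99 within R prefix tumours, and 0 lists with an estimated correlation or by fry. For p53 there were 22 after centring, 19 with the mean of probe sets, 31 with an intensity trend and a robust prior together and 395 with array weights. At least 2-fold there were 27, with only the groups compared 26 and without arrays of low correlation 103. With the animal number form as a block there were 0, and within it 0 (and 2 lists). Within it the 47 genes had a median of 1.04 in their direction, but they were selected on the same p53 m/fl tumours. For B2 against B1 there were 2 after quantile normalization, 2 after centring, 0 with the mean of probe sets, 0 with an intensity trend and a robust prior together, 0 with only the groups compared, 340 with array weights and 91 without arrays of low correlation, and 1 list with the mean of probe sets, with only the groups compared and without those arrays. For stage there were 10 lists after centring, 3 with the dimmest genes left out, 11 in B1 fl/fl p53 fl/fl tumours only, and 0 with an estimated correlation or by fry.

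Leaving out single replicates gave 5886 (without normal sample 3) to 7874 genes and 11 to 13 lists for tumours against normal epithelium, 0 to 12 genes and 7 to 13 lists for B1, 4 to 51 genes and 0 lists for p53, 0 to 22 genes and 0 to 1 lists for B2 against B1, and 0 genes and 4 to 7 lists for stage, with 0 for the interaction. Per genotype the ranges were 5630 to 5776, 5042 to 5803, 3134 to 3903 and 5197 to 6885.

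Some medians reversed. With the dimmest genes left out that of T and NK cells was 1.34. With the Gapdh covariate Esrp1 was 0.37, Sox17 1.56, Akr1c18 0.86 and Egln3 −0.045. For B1, leaving out single K18 tg replicates gave interferon from −0.39 to 0.15 (without replicate 1), mitosis from −0.013 (without replicate 3) to 0.36, and neutrophils from −0.64 to 0.24 (without replicate 3). Within six-digit tumours mitosis was −0.077, T and NK cells 0.14, B and plasma cells 0.091, macrophages 0.35, neutrophils 0.52, fibroblasts 0.49, smooth muscle 0.38, adipocytes 0.35 and mesenchymal transition 0.083. For stage in B1 fl/fl p53 fl/fl tumours only, replication was −0.12, mitosis −0.14, homologous recombination −0.044, macrophages 0.32 and immediate early genes 0.27.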

Other observations

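Chosen only after the results were seen were the 10 further lists used here and the comparisons of small nucleolar RNA host genes and the respiratory chain. Cholesterol synthesis genes were lower in tumours than in normal epithelium, 12 of 15 with 0 higher (median log2 difference −1.10, camera adjusted p = 0.000720, and adjusted p = 0.413 with an estimated correlation), among them Msmo1 (−1.83), Idi1 (−1.80) and Fdft1 (−1.59). Theca and luteal genes, of cells that make cholesterol, fell in the same comparison (list mean 11.56 ± 0.95 (SD, n = 3) in normal epithelium and 7.69 to 8.08 in the replicated tumour groups), so a fall within tumour cells is not shown. Polycomb and DNA methylation genes were higher, 8 of 16 with 1 lower (median 0.50, camera adjusted p = 0.00216, and adjusted p = 0.119 with an estimated correlation), among them Tet2 (1.55), the methyltransferase Ezh2 (1.32) and Dnmt3b (1.12). Ribosomal protein genes were lower, 21 of 43 with 1 higher (median −0.16, camera adjusted p = 0.00570, and adjusted p = 0.685 with an estimated correlation). The median over all genes was −0.11 and moved by 0.13 with quantile normalization, so this fall is not told apart from scaling. Of 33 Hox genes 12 were lower and 0 higher, which was not called as a list (median −0.30, adjusted p = 0.0805), with Hoxd10 at −6.24, Hoxd9 at −4.48 and Hoxd8 at −3.88. Further oocyte transcripts passed camera (adjusted p = 6.19e-14, and adjusted p = 0.0495 with an estimated correlation).

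Not called between tumours and normal epithelium were Wnt targets (2 of 15 higher, 4 lower, adjusted p = 0.740), with Rnf43 at 1.70 and Axin2 at 1.18, the respiratory chain (6 of 77 higher, 28 lower, adjusted p = 0.241), host genes of small nucleolar RNAs (4 of 17 higher, 4 lower, adjusted p = 0.626), complement and coagulation (1 of 14 higher, 2 lower, adjusted p = 0.866) and further fat cell transcripts (2 of 23 higher, 7 lower, adjusted p = 0.626). Of 23 further fat cell transcripts 0 were called between B1 fl/fl and K18 tg tumours with p53 fl/fl, and the list passed camera only at its preset correlation (median −0.45, camera adjusted p = 2.57e-12, and adjusted p = 0.0583 with an estimated correlation).

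Of 17 host genes of small nucleolar RNAs 3 were called lower in B1 fl/fl p53 m/fl than in B1 fl/fl p53 fl/fl tumours and 14 were not called. The list was drawn up after these falls were seen and includes them, so no test of the whole list is given. The mean of the 14 host genes not called was 8.77 ± 0.33 (SD, n = 3) against 9.56 ± 0.31 (n = 14), and 9.50 ± 0.43 (n = 5) in B2 fl/fl p53 m/fl tumours. B1 fl/fl p53 fl/fl replicate 11 also had a mean of 8.77. A shift of the class as a whole may underlie the calls of Snhg3, Snhg5 and Gas5: the host genes that were not called all lay below 0, with a median of −0.823, below that of all 10000 random lists of like expression. Those lists draw genes singly, so this rank does not measure the spread between tumours. In stage IV against lower stages the median of the 17 host genes was 0.32, with 0 called. Of the B1 fl/fl p53 m/fl tumours 1 is of stage IV and 2 are lower. For the staged B1 fl/fl p53 fl/fl tumours these numbers are 8 and 3, so stage is not told apart here. Of 77 respiratory chain genes 0 were called between these groups, and the list passed camera only at its preset correlation (median 0.24, camera adjusted p = 4.37e-15, and adjusted p = 0.118 with an estimated correlation). No biological explanation was tested. Among the other tumours with animal numbers of 2 to 5 digits, B1 fl/fl p53 fl/fl replicates 1 and 2 had means of 9.89 and 9.23 for the 14 host genes not called, and B2 fl/fl p53 m/fl tumours from 8.91 to 10.1.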
